A study of Mus musculus with 2 samples.

How the data were processed

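Total RNA from G1E-ER4 cells treated with 10 nM estradiol for 24 h was sequenced in 2 libraries, which the labels give as biological replicates 1 and 2 of a single group. The labels state a size range above 200, with no unit. Each library has a gene table and a transcript table, and all values here come from those tables.

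Per the labels the assembly was mm10, and the annotation was GENCODE M4 per the file headers of the deposited documentation. The columns carry the names that RSEM writes, but the quantifier's version, the aligner and any trimming are not given in the sources used here. The expected counts deposited by the authors are estimated reads or fragments per gene, shared out among overlapping and repeated sequences, and are not normalized. The deposited TPM values are scaled by the authors to a fixed total over all listed features, spike-ins included. The deposited FPKM values are scaled by the authors per kilobase of effective length and by library depth. The transcript shares are percent values deposited by the authors, each transcript's part of its gene's TPM. Posterior mean TPM and counts were also deposited and were used only as alternatives. Effective length was 119 nt shorter than length in replicate 1 and 123 nt shorter in replicate 2, so genes shorter than that have little or no effective length.

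Each gene table holds 69691 entries. Of these 43346 are Ensembl genes, 96 are ERCC spike-ins, 1 is phiX and 26248 carry a bare number as identifier. Genes were named from GENCODE M21 (mm10 coordinates) by identifier without its version, which matched 42462 genes. The other 884 kept their identifiers and entered gene totals without a class. RNA classes followed M21 gene types. Gm42418 and Gm26917 were set apart as a class after the data were seen, because of their level. Of 249 members of 20 gene lists, 247 were matched, and the other 2 were not analysed here.

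With 1 group there is no contrast, so levels are given as the mean ± SD of both libraries. A gene was called detected at a TPM of 1 or more in both. Log2 ratios are replicate 2 over replicate 1 with a pseudocount of 0.1, which understates differences of low genes. A list's median TPM was ranked among 10000 random protein-coding lists, and its median log2 ratio among 10000 lists drawn within 50 ranks of each member's mean TPM. The biological coefficient of variation came from edgeR 4.0.16 in R 4.3.3 (estimateDisp, intercept only, TMM, filterByExpr) on expected counts rounded to whole numbers. DESeq2 1.42.0 gave alternatives. Sequence identity was measured with BLAST+ 2.17.0 on M21 transcripts. The rest used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

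The edgeR step was tested on simulated counts with the real means and depths. Without changed genes, true coefficients of 0.05, 0.1 and 0.3 gave estimates of 0.0500, 0.100 and 0.295 over 11213, 11217 and 11086 genes. With 200 genes changed 4-fold, a true value of 0.1 gave 0.163, so genes that differ strongly raise the estimate. In that simulation 99.5% of the changed genes came out 2-fold or more apart. These genes were drawn only from protein-coding genes above a minimum mean count and compared on counts scaled by TMM. The share therefore does not apply to short or low-count genes, or to ratios of TPM.

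Gene lists, gene pairs, thresholds and the rule for named genes were set before the data were examined. The rule took up to 4 of the highest and up to 2 of the lowest members of each list and the genes of 8 pairs. It also took the 10 highest protein-coding nuclear genes, the 10 highest others, the 5 highest and 5 lowest log2 ratios at a mean TPM of 5 or more, and 10 genes for transcripts. Some results that the rule names are not reported here. Ties at 0 were named only in part. Genes named outside the rule were chosen after their values were seen. Alternatives changed the TPM threshold, pseudocount, filters, unit, scaling and denominator, and left out each replicate. The 50277914 and 47478888 expected counts come from reads without molecular identifiers, so floors of 3 counts cover counting error only.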

Results

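Total RNA was sequenced from G1E-ER4 cells, a mouse erythroid line that lacks its own Gata1 function and carries a restored, estradiol-dependent GATA1. The cells had been treated with 10 nM 17β-estradiol for 24 h, the treatment that starts their erythroid differentiation. The series holds 1 group with 2 biological replicates and no untreated group, so the values describe levels in the induced cells and how far the 2 cultures agreed. No change with treatment was measured, and no p-value is given, because there is no contrast to test. The expected counts summed to 50277914 in replicate 1 and 47478888 in replicate 2, of which 14373925 and 13901316 fell on nuclear protein-coding genes. Across 8285 nuclear protein-coding genes with 200 or more counts, the libraries differed by 7.83 times the chi-square that sampling noise alone gives, so they were treated as separate libraries.

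The libraries were dominated by ribosomal RNA-related loci. Gm42418 is a non-coding gene on chromosome 17 (39846958 to 39848788, mm10). It overlaps the RefSeq 18S ribosomal RNA related sequence Rn18s-rs5 (39846354 to 39848202) over 1245 bases. Gm42418 and its neighbour Gm26917 together took 55.0% ± 1.11 of the expected counts (SD, n = 2). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took a further 11.8% ± 0.511. Nuclear protein-coding genes other than histones held 28.7% ± 0.518, mitochondrial mRNAs 2.54% ± 0.145, pseudogenes 0.941% ± 0.0438, small RNAs 0.397% ± 0.00387, other long non-coding RNAs 0.348% ± 0.0150 and histone genes 0.277% ± 0.0301 (SD, n = 2 for each). On the TPM scale Gm42418 alone stood at 482979 ± 11156 (SD, n = 2). TPM is a share of the whole library, so every other TPM here is lowered by these RNAs. Nuclear protein-coding genes summed to 22.7% of TPM in replicate 1 and 22.9% in replicate 2, and a TPM over these genes alone would be 4.41 and 4.37 times higher.

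**Figure D1:**
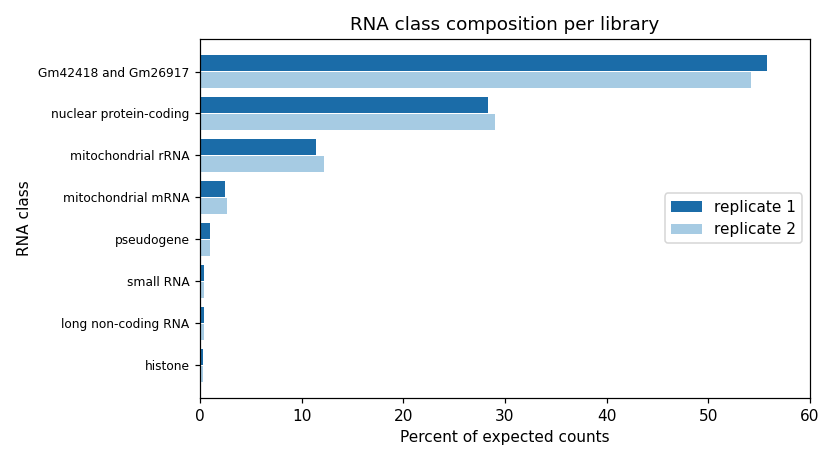
Percent of expected counts (horizontal axis, from 0) in each RNA class (vertical axis) for replicate 1 (dark bars) and replicate 2 (light bars). Gm42418 and Gm26917 held 55.7% and 54.2%, and nuclear protein-coding genes other than histones 28.3% and 29.0%.

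A total of 9570 annotated genes had a TPM of 1 or more in both replicates, 8620 of them nuclear protein-coding genes out of the 21461 listed. The protein-coding nuclear genes with the highest mean TPM were Eef1a1 (5096 ± 151), a translation elongation factor, and Gapdh (4048 ± 8.01), a glycolytic enzyme (SD, n = 2). They were followed by the histone gene Hist1h4d (2387 ± 195), the mitochondrial leucyl-tRNA synthetase Lars2 (1854 ± 13.99), and the ribosomal protein genes Rpl4 (1550 ± 79.2), Rps26 (1530 ± 55.4) and Rpl17 (1489 ± 56.7). Pabpc1 (1222 ± 128), a poly(A)-binding protein, Npm1 (1195 ± 12.4), a nucleolar protein, and Ptma (1012 ± 78.1) completed the first 10. Apart from Gm42418, the highest nuclear genes that do not encode protein were Rn7sk, the 7SK RNA that restrains transcription elongation (13829 ± 363), Gm10925 (6933 ± 1821), Gm26917 (5275 ± 141), Mir6236 (5204 ± 318) and Rpph1, the RNA of RNase P (4660 ± 191). Mir6236 is 123 nt long, close to the 119 and 123 nt by which effective length was shorter than length. Its TPM therefore rests on a short effective length, with 3307 counts in replicate 1 and 2646 in replicate 2. Neither Mir6236 nor Lars2 was compared with ribosomal RNA sequences, so reads of ribosomal RNA in their values are not excluded. Rpph1 had 31647 and 27850 counts. Rn7s1 and Rn7s2 carry the same sequence over 300 nt and were each listed at 4353 ± 1.51. The chromosome 1 pseudogenes Gm10222 (3377 ± 1602) and Gm29216 (2835 ± 25.1) followed (SD, n = 2 for each). Gm10925 and Gm10222 are 100% identical to the mitochondrial genes mt-Atp6 and mt-Nd4l over 678 and 294 aligned bases. Their listed levels therefore do not show that the nuclear copies were transcribed. Gm29216 lies near them (chromosome 1, 24615706 to 24616197) and was not compared with a mitochondrial gene, so its level does not show this either.

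Adult globin genes were transcribed and embryonic ones were at or near 0. Hbb-bs, an adult beta-globin gene (ENSMUSG00000052305.5, chromosome 7, 103826534 to 103828096, mm10), had a TPM of 1001 ± 10.3 (SD, n = 2). The alpha-globin genes Hba-a2 and Hba-a1 had 159 ± 4.14 and 121 ± 7.53, and Hbb-bt had 44.7 ± 8.70. The copies within Hba-a1 and Hba-a2, and within Hbb-bt and Hbb-bs, are nearly identical, so the split between them is uncertain. The listed ratio was 0.0447 ± 0.00915 for Hbb-bt over Hbb-bs and 0.759 ± 0.0669 for Hba-a1 over Hba-a2. Of the embryonic genes, Hbb-bh1 had 36 counts in replicate 1 and 12 in replicate 2, while Hbb-y, Hbb-bh2 and Hba-x had no read. Embryonic genes made up 0.211% of beta-like globin TPM in replicate 1 and 0.0744% in replicate 2, a mean of 0.143% ± 0.0966. All 10 globin genes together held 0.133% ± 0.000375 of TPM, or 0.584% ± 0.00178 of the TPM of nuclear protein-coding genes (SD, n = 2). Summed alpha-globin TPM was 0.268 ± 0.00284 of summed adult beta-globin TPM.

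All 9 heme synthesis genes were detected at a TPM of 1 or more in both replicates. Their median TPM of 21.9 stood at the 99.9th percentile of 10000 random protein-coding lists of equal size. These lists were drawn from all 21461 listed nuclear protein-coding genes, of which only 8620 were detected, so a list of expressed genes ranks high. Cpox, which makes protoporphyrinogen in the mitochondrion, led at 362 ± 1.23. Fech, the ferrochelatase, had 90.0 ± 2.88 and Urod 27.4 ± 0.785 (SD, n = 2). Uros had 4.53 ± 0.0707. The erythroid first-step enzyme Alas2 had 10.7 ± 0.141 and its housekeeping counterpart Alas1 5.58 ± 1.27, a ratio of 1.97 ± 0.475. All 15 iron handling genes were detected, with a median TPM of 14.4. The ferritin chains Ftl1 (559 ± 7.65) and Fth1 (502 ± 24.3) and the transferrin receptor Tfrc (160 ± 6.07) led, with the sorting nexin Snx3 at 135 ± 10.3. The heme oxygenase Hmox1 (4.59 ± 0.700) and the iron exporter Slc40a1 (10.0 ± 0.940) were lowest. Tfrc exceeded Tfr2 by 8.57 ± 0.893 times.

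Of the 19 red cell membrane genes measured, 15 were detected, with a median TPM of 18.6. The Rh-associated glycoprotein Rhag (92.5 ± 0.820), Cd47 (86.7 ± 1.85), the protein 4.1 gene Epb41 (64.6 ± 5.68) and the Ermap blood group protein gene (64.1 ± 1.90) were highest (SD, n = 2). The tropomodulin gene Tmod1 stood at 0.50 ± 0.028, and Aqp1, a water channel, had no read in either replicate.

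All 17 erythroid regulators were detected, with a median TPM of 26.9, above all 10000 random lists. High medians were not limited to erythroid lists: the percentile was also 100 for the cell cycle list, 99.9 for survival and 99.7 for autophagy genes. It was 100 for red cell membrane and 99.95 for iron handling genes, while globins stood at 78.6 and progenitor genes at 89.4. Gfi1b, a transcriptional repressor, was highest at 122 ± 0.424, followed by Lmo2 at 81.9 ± 1.03, Nfe2 at 80.3 ± 3.83 and the GATA1 cofactor Zfpm1 at 72.0 ± 2.98 (SD, n = 2). E2f2 (7.76 ± 1.55) and Zbtb7a (7.16 ± 0.502) were lowest. Gata1 (ENSMUSG00000031162.10, X chromosome, 7959260 to 7978071, mm10) had 61.6 ± 5.74, and Klf1 26.9 ± 2.98. The tables give 1 value for Gata1, so reads of the restored copy and of the cells' own locus are not separated in it.

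The progenitor list was uneven, with a median TPM of 2.76 and its 4 highest members between 76.9 and 127. The stem cell factor receptor Kit (chromosome 5, 75574916 to 75656722, mm10) had a TPM of 127 ± 0.643, Myb 105 ± 8.73, Myc 103 ± 4.79 and Gata2 (chromosome 6, 88193891 to 88207032, mm10) 76.9 ± 2.26 (SD, n = 2). Of the 17 progenitor genes 10 were detected, Meis1 (0.455 ± 0.0778) and Cd34 (0.050 ± 0.014) were not, and Hoxa9, Ly6a, Mecom and Cebpa had no read. Gata1 over Gata2 was 0.734 in replicate 1 and 0.873 in replicate 2, a mean of 0.803 ± 0.0984, and 0.458 on expected counts, which are not divided by length. Klf1 over Spi1, the myeloid PU.1 gene, was 1.47 ± 0.207, and the erythropoietin receptor gene Epor stood at 0.0705 ± 0.000190 of Kit on TPM and at 0.0254 on expected counts.

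The 17 cell cycle genes were all detected, with a median TPM of 57.7. Mcm3 (240 ± 4.12), Mki67 (148 ± 4.96), Mcm6 (107 ± 1.29) and Top2a (91.5 ± 1.34) led, and Cdk1 (19.8 ± 0.474) and Ccne1 (10.1 ± 1.87) were lowest (SD, n = 2). Of the 12 cell cycle inhibitors 9 were detected, led by Rb1 (60.4 ± 0.113), Cdkn1a (38.4 ± 2.40), Rbl1 (21.6 ± 0.658) and Rbl2 (17.4 ± 0.841). Cdkn2a and Cdkn2b had no read. Of the 14 autophagy genes 13 were detected. Bnip3l, a mitophagy receptor used in red cell maturation, had 298 ± 8.22, Gabarap 136 ± 9.48, Bnip3 82.1 ± 3.71 and Sqstm1 20.1 ± 1.81, while Wipi1 had 2.81 ± 0.325 and Map1lc3a 0.210 ± 0.170. Of the 9 survival and apoptosis genes 8 were detected, led by Mcl1 (60.9 ± 0.849), Bak1 (57.3 ± 2.07), Bax (24.9 ± 0.778) and Pim1 (20.3 ± 1.38). Bbc3 (2.38 ± 0.120) and Bcl2 (0.825 ± 0.247) were lowest. Bcl2l1, which encodes BCL-XL, exceeded Bcl2 by 11.2 times in replicate 1 and 18.03 times in replicate 2, and by 6.00 times on expected counts.

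Of the 7 estrogen receptor genes and classical target genes only Nrip1 was detected (14.5 ± 1.03), and 5 had no read, among them Esr2, Gper1, Greb1 and Tff1. Esr1 had 26 counts in replicate 1 and 4 in replicate 2. Of the 9 stress genes 4 were detected, Egr1 (19.4 ± 1.25), Hsph1 (17.1 ± 0.332), Ddit3 (15.6 ± 0.990) and Dnajb1 (15.1 ± 1.30). Atf3 had no read and Hspa1a 0.010 ± 0.014 TPM. Among 12 non-coding RNA genes measured, Rmrp (1355 ± 173) and Malat1 (542 ± 37.4) followed Rn7sk and Rpph1 (SD, n = 2). Mir144 and Mir451a are listed at 0, but both are shorter than the fragments and have no effective length in the tables, so no level can be read from them.

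Markers of other cell types were mostly at or near 0. In 7 such lists, 8 of 80 genes reached a TPM of 1 in both replicates, and 41 had no read in either. With TPM rescaled over nuclear protein-coding genes, 9 of 14 megakaryocyte genes and 4 of 12 mast cell and basophil genes reached 1. So did 1 of 17 granulocyte and macrophage genes, and the other lists kept their counts. Of the megakaryocyte genes 4 of 14 were detected, but 9 at a TPM threshold of 0.5 and 2 at a threshold of 5. The platelet factor Pf4 had 18.96 in replicate 1 and 10.54 in replicate 2, Itga2b 6.34 ± 0.841, Gp1ba 4.12 ± 0.424 and Gp5 1.99 ± 0.0778, while Thbs1 and Selp had no read. Of the mast cell and basophil genes 3 of 12 were detected. The mast cell protease Cpa3 had 27.4 ± 0.912, Cd200r3 2.65 ± 0.0354 and Hdc 1.91 ± 0.0212, Ms4a2 had 1.01 ± 0.134, and Mrgprb2 and Prss34 had no read. Gata3 (2.96 ± 1.13) was the only detected gene of 11 T and NK cell genes, where Lck had 0.375 ± 0.417 and Cd3g 0.135 ± 0.00707. None of 17 granulocyte and macrophage genes, 8 B cell genes, 10 stromal and endothelial genes or 8 pluripotency genes was detected in both replicates. Among them Pecam1 had 11 counts in replicate 1 and 0 in replicate 2, and Nanog 6 and 2. A count of 0 leaves room for 3 counts, which for a gene with 1 kb of effective length is a TPM of 0.0910 in replicate 1 and 0.0957 in replicate 2. This floor covers counting error only.

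**Figure D2:**
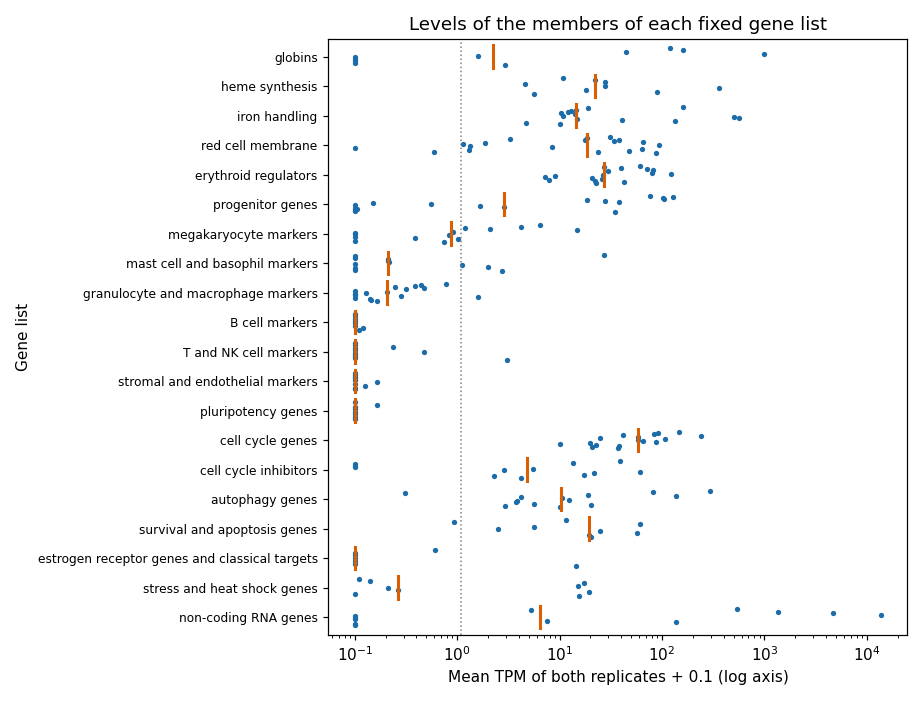
Mean TPM of both replicates plus 0.1 (horizontal log axis) for every measured member (blue points) of each of the 20 fixed gene lists (vertical axis), with the list median as an orange bar and a dotted line at a TPM of 1. All members of the heme synthesis, iron handling, erythroid regulator and cell cycle lists lie to the right of the line, and most B cell, stromal and pluripotency genes lie at 0.

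The granulocyte and macrophage list differed between the replicates at low counts. Mpo, the myeloperoxidase gene, had 1 count in replicate 1 and 70 in replicate 2, Elane 0 and 17, Ly6c2 0 and 14, and Cd68 22 and 53. Their TPM stayed at 2.08 or lower in every library. The median log2 ratio of the list (replicate 2 over replicate 1) was 0.85, at the 99.9th percentile of 10000 lists matched on mean TPM. The middle member was S100a9, with 0 counts in replicate 1 and 1 in replicate 2. This median therefore rests on 1 count and on the pseudocount. The progenitor list had a median log2 ratio of -0.06, at the 0.440th percentile, and the red cell membrane list 0.09, at the 94.5th. These percentiles describe the 2 libraries and have no replicate check.

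Replicate agreement differed with gene length and count. Across 10041 genes with a mean TPM of 1 or more, the log2 ratio of TPM + 0.1 (replicate 2 over replicate 1) had a median of 0.03 and an SD of 0.83. Pearson's r across these genes was 0.905 and Spearman's rho 0.958, although genes are not independent replicates. Among 8808 nuclear protein-coding genes, the SD was 0.37 and r was 0.977. Of 238 genes shorter than 200 nt, 155 differed 2-fold or more, against 134 of 8263 genes of 1000 nt or longer. The median count was 4.21 in the first of these groups and 685.5 in the second, so length and count were not separated. In all, 475 genes differed 2-fold or more, 248 higher in replicate 2 and 227 higher in replicate 1, and 172 of the 475 were nuclear protein-coding. The common biological coefficient of variation was 0.125 by edgeR over 10926 genes. It was 0.109 over nuclear protein-coding genes alone, and 0.0451 by the median DESeq2 gene-wise dispersion over the genes first used. Of all 10041 genes, 768 (7.65%) lay outside the 95% range that the common value and counting noise give, among them 328 of the 475.

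The most unequal genes with a mean TPM of 5 or more were short non-coding RNAs, 8 of the 10 with 14 counts or fewer. Snord70, Snord14a, Snord16a, Gm23053 and n-R5s40 had no count in replicate 1 and 3, 1, 3, 2 and 9 counts in replicate 2. Gm24924 and Gm26244, annotated as small nuclear RNAs of 164 nt, were each listed at 173.75 counts in replicate 1 and 0 in replicate 2. Their sequences were not compared, so these equal values may be shared reads, and a 0 may reflect how reads were divided. Gm25864 had 10 and 0 counts, Mirlet7d 9.57 and 0, and Rny1 14 and 0. These genes are all shorter than 200 nt, and the labels give the RNA size range as above 200, with no unit.

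**Figure D3:**
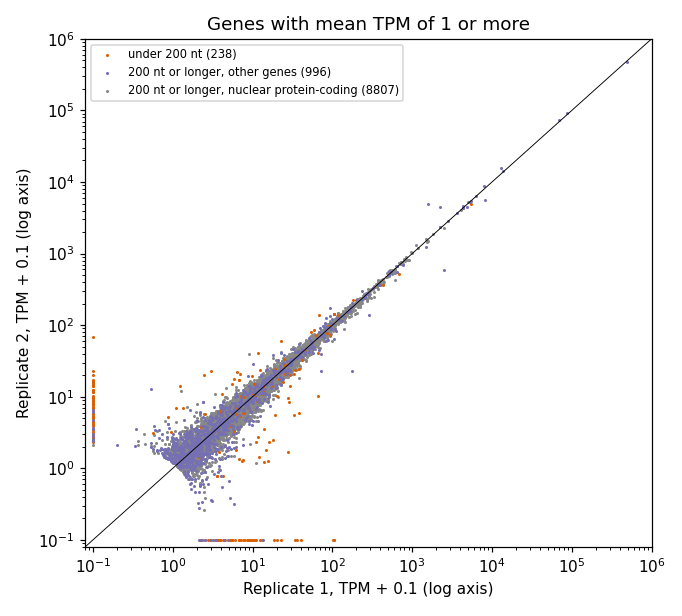
TPM + 0.1 in replicate 1 (horizontal log axis) against replicate 2 (vertical log axis) for the 10041 genes with a mean TPM of 1 or more, coloured by length and class, with the line of equality. Genes under 200 nt (orange) include many at 0 in one library, along the edges, while nuclear protein-coding genes (grey) lie along the line with an SD of 0.37 in the log2 ratio.

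Transcript shares were estimated for a fixed set of erythroid genes. Klf1 has 1 annotated transcript, and Gata1-201 held 99.2% ± 0.615 of Gata1 TPM, Tal1-201 98.9% ± 0.566 of Tal1 and Lmo2-208 95.1% ± 0.226 of Lmo2 (SD, n = 2). Alas2-201 held 92.8% of Alas2 TPM in replicate 1 and 72.3% in replicate 2, but 98.6% and 89.6% of its expected counts. The 569 nt transcript Alas2-204 had 0 counts in replicate 1 and 30.1 in replicate 2, so the TPM difference rests on few counts. Bcl2l1-201, the leading Bcl2l1 transcript, held 77.4% ± 3.02. For Epb41 the leading transcript, Epb41-215 (59.4% ± 6.48), is annotated as a processed transcript without a coding sequence. Runx1-201 (34.1% ± 1.75) and Runx1-207 (32.5% ± 2.36) lay within the spread between replicates of each other on TPM, but on expected counts, which are not divided by length, they held 56.0% and 22.5%. Ldb1-201 held 44.8% of Ldb1 in replicate 1 and 31.5% in replicate 2, where Ldb1-205 held 33.4%, so the leading transcript of Ldb1 was not the same in both. Nor was that of Runx1, where Runx1-207 held 34.2% and Runx1-201 32.9% in replicate 1.

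Spike-in RNAs took 0.00144% ± 0.000206 of the expected counts (SD, n = 2). Of 96 ERCC sequences, 12 had counts in replicate 1 (653 in total) and 17 in replicate 2 (755 in total), too few for a dose curve. The phiX sequence had 0 counts in both.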

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

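The tests of summed copies, of the globin share and of the rank of Hbb-bs were chosen after those results were seen. The other tests were written down before. No biological explanation was tested for the globin pattern, since the study has a single group.

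Entries with a bare number as identifier, outside the genes analysed, had 5 expected counts in replicate 2 and 0 in replicate 1. It is noted because it exceeds the 3 counts that a count of 0 allows, which does not show a difference between the libraries.

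mt-Atp6 and mt-Nd4l differed between the replicates in opposite directions. mt-Atp6 had a TPM of 1559 in replicate 1 and 4948 in replicate 2 (log2 ratio 1.67), and mt-Nd4l 2503 and 581 (log2 ratio -2.11), while the 11 other mitochondrial mRNAs had an SD of 0.36, or 0.18 without mt-Co2 (log2 ratio 1.15), which also has an identical chromosome 1 copy. The chromosome 1 pseudogenes Gm10925 and Gm10222 moved the opposite way, and each is 100% identical to its mitochondrial gene over 678 and 294 aligned bases. A change in the mRNAs themselves would give the sum of mt-Nd4l and Gm10222 a log2 ratio of -0.75 with the pseudogene held fixed, but it was 0.10, which argues against it. The larger of both summed log2 ratios was 0.12 in size, so reads divided differently between identical copies may account for the pattern.

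The granulocyte and macrophage list had 62 counts in replicate 1 and 207 in replicate 2. Of its 17 genes, 10 were higher in replicate 2 and 3 higher in replicate 1. Cd68 gave 22 and 53 of these counts and Adgre1 19 and 18, so the totals are not of granulocyte genes alone. RNA of granulocyte precursors in replicate 2 could account for higher counts of granulocyte genes, but Prtn3 went from 8 to 5 counts and Lyz2 from 10 to 6. In a separate list of 14 precursor genes, 6 were higher in replicate 2 and 2 in replicate 1, and the mean log2 ratio was at the 66.8th percentile of matched lists, which decides neither way. Amplification copies of few molecules could also do it: 5.06% of 1028 protein-coding genes with 20 to 120 counts, Mpo among them, differed 10-fold or more (52 genes, 95% Wilson interval 3.88% to 6.57%). Counting noise alone would give 0.00595 such genes. Some of the 52 have fractional counts, such as Gm28048 (0 and 113.66), so the share also holds reads divided among similar sequences. The labels give a starting quantity of 1 ng for both libraries, and whether this is the RNA input is not certain. The share just meets the 5% set beforehand, and its interval, added after it was seen, reaches below that. Differences between the cultures could give such a share as well. The test therefore does not decide on amplification, and both granulocyte precursors and amplification stay open.

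Globin genes held 0.133% of TPM while Kit, Myb, Myc and Gata2 had a mean TPM of 127, 105, 103 and 76.9. Ribosomal RNA taking most of the TPM lowers every other share. Globin genes held 0.584% of nuclear protein-coding TPM, where that RNA is left out. This is the same share rescaled by known factors, so it cannot decide for or against this explanation. It shows only how large the share is with that RNA left out. Loss of short mRNAs was looked for in the 89 detected ribosomal protein genes, where length and TPM had a Spearman rho of -0.195 across genes. This was not the positive value predicted for such a loss. The true levels of these genes are not known, so the test does not decide. Cultures that were not fully induced, or that carry a wrong label, cannot be told apart from an early stage of differentiation without an untreated library. Hbb-bs still ranked 11 among nuclear protein-coding genes, which leaves both open.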

How the results depend on the processing

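No paired analysis was possible because the series has a single group. Leaving out a replicate cannot give a replicate ratio or a coefficient of variation, and for a mean of both the lone replicate lies within 1 SD by construction. For list medians and detected members it need not: 6 of 80 such values moved. Of these, 2 were for the cell cycle median (54.8 and 54.0 against 57.7). The others were 1 each for the iron handling (14.7), megakaryocyte (0.68) and survival (18.6) medians and the granulocyte and macrophage genes detected (2 against 0). Of 340 alternative values, 257 kept within 1 SD (counts within 1.5 times, the coefficient of variation within 5%, the SD of the log2 ratio within its bootstrap SD over genes), and 83 moved. No pair ratio crossed 1, and the other values have no sign to reverse, but the leading transcript of Ldb1 and of Runx1 differed between the replicates. Among lists, transcripts and small classes 53 of 255 moved, 17 of them with TPM rescaled over nuclear protein-coding genes. The 7 genes-detected alternatives gave 6357 at a TPM of 5 and otherwise 8953 to 11093. The SD of the log2 ratio was 0.49 with a pseudocount of 1, 1.18 with 0.01, 0.94 with no filter, 0.50 at a mean TPM of 10, 0.77 on FPKM and 0.62 on rounded expected counts scaled by TMM. Alternatives chosen after seeing the data gave 0.37 for nuclear protein-coding genes and 0.49 for genes of 200 nt or longer. Genes 2-fold or more apart numbered 300 with a pseudocount of 1, 2024 with no filter, 42 at a mean TPM of 10 and, chosen after seeing the data, 172 among nuclear protein-coding genes. The coefficient of variation was 0.158 with no filter, 0.109 for nuclear protein-coding genes, 0.0451 by the median DESeq2 gene-wise dispersion and 0.142 by its fitted one. The cause was not tested. The globin share became 0.584% when rescaled over nuclear protein-coding genes, by construction, and 0.0397% of expected counts. On expected counts, which are not divided by length, the pair ratios were 0.0592 for Hbb-bt over Hbb-bs, 0.922 for Hba-a1 over Hba-a2, 0.458 for Gata1 over Gata2, 6.00 for Bcl2l1 over Bcl2, 1.26 for Klf1 over Spi1, 0.0254 for Epor over Kit and 9.52 for Tfrc over Tfr2. On TPM, Gm42418 and Gm26917 held 48.8%, nuclear protein-coding genes other than histones 21.7%, mitochondrial ribosomal RNA 16.1% and spike-ins 0.00277%. Depth limits genes under 3 counts and the spike-ins.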

Other observations

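Histone and ribosomal protein genes were among the abundant mRNAs. Of 65 histone genes 55 were detected, holding 1.02% ± 0.111 of TPM, and of 98 ribosomal protein genes 89 were detected, holding 2.85% ± 0.00824 (SD, n = 2).

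Mitochondrial mRNAs differed widely in listed TPM. mt-Atp8 had a TPM of 14478 ± 1938, mt-Nd2 8359 ± 516, mt-Cytb 6401 ± 22.5 and mt-Co1 5480 ± 49.3, while mt-Nd6 had 733 ± 41.4 and mt-Nd3 114 ± 29.0 (SD, n = 2). mt-Atp8 is 204 nt long, so its TPM rests on a short effective length. It also overlaps mt-Atp6 (7766 to 7969 against 7927 to 8607), so its entry does not give a separate level. mt-Co2 was listed at 14.1 ± 7.62, and its chromosome 1 copy Gm28661, 100% identical over 681 aligned bases, at 2237 and 2370. mt-Co3 was listed at 544 ± 6.35, and its copy Gm28437, 100% identical over 783 aligned bases, at 511 and 500. The levels of mt-Co2 and mt-Co3 therefore cannot be read from their own entries. The other mitochondrial mRNAs named here were not compared with chromosome 1 sequences.

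Some protein-coding genes with 200 or more counts in total also differed between the replicates. Gm10800 had 21 counts in replicate 1 and 202 in replicate 2 (log2 ratio 3.24), and Gm14308 had 210 and 39.0 (log2 ratio -2.11). Rogdi had 122 counts in replicate 1 and 282 in replicate 2, Atp5l 59.6 and 159, and Vps51 293 and 150. These genes were chosen after their values were seen, and a difference between 2 libraries has no replicate check.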
